A study of Halobacterium salinarum NRC-1 with 6 samples.

How the data were processed

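RNA of 3 samples of Halobacterium salinarum NRC-1 exposed to manganese sulphate (0.8, 1.0 and 1.5 mM, 5 h) was hybridised against a standard control on 6 arrays of 2 colours, per the labels. Each dose had 1 array with the exposed RNA in Alexa 532 (channel 1, replicate 1) and 1 with it in Alexa 647 (channel 2, replicate 2). The 2 arrays of a dose are a technical dye swap of the same RNA pair and were counted as 1 sample, so n = 3.

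The only values used are the log ratios the authors deposited, 1 per spot, in a table of 10752 spots by 6 arrays. Scanner intensities were not used here. The background correction, normalization, log base, numerator and centring of the deposited log ratio are not given in the sources used here. The values have both signs, and the array medians run from 0.0866 to 0.116, so they were not centred on 0. The base could not be recovered, and sizes are therefore given in the deposited unit.

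The probe annotation, which may be old, paired 532 spots with 1 gene symbol each, 133 genes in all, and 0 spots with several symbols. It left 10220 spots unnamed here. Every named gene had 4 spots, a pair of adjacent ones in each of 2 blocks of the array. The same layout was applied to the unnamed spots, which gave 2688 features. For unnamed features the blocks correlated at 0.516 to 0.835 per array, and at 0.105 to 0.258 when the layout was shifted by 1 feature. All 131 named genes tested were also found by symbol in the RefSeq annotation of another strain, Halobacterium salinarum 91-R6 (assembly ASM479960v1). It was used only for which genes neighbour each other, and no coordinates are given.

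Exactly 0 was listed on 1034 spots (9.62%) of 1 array, replicate 1 at 1.5 mM, and on none of the other arrays. The other arrays averaged 0.314 at those spots and 0.0921 elsewhere, so these values were treated as missing. Of the 437 features with such a spot, 101 lost all 4 spots and were not tested, which left 2587.

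The sign of the arrays with manganese RNA in channel 2 was turned, and the 2 arrays of a dose were then averaged. This departs from a rule written before the data were examined, under which pairs that correlate above 0 would have been used as deposited. The pairs correlated at 0.602 to 0.624. That rule overlooked a bias common to both orientations. The difference between the 2 blocks of the array, which hold the same probes and so carry no biology, correlated at 0.607 on average over the 9 pairs of arrays of opposite orientation (0.438 to 0.761). Values already turned by the authors would make it negative. It was not a scaled copy of the feature's own value either, since it correlated with the common part by at most 0.0769 in size. The part common to both orientations correlated at 0.942 to 0.963 between doses, with an SD of 0.117 to 0.145, and the turned part at 0.592 to 0.771, with an SD of 0.0578 to 0.0733. The unturned reading is kept as an alternative. A positive value is called likely exposed over control because the labels word each array as channel 1 against channel 2.

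Spots of a feature were averaged within an array. Features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided): the mean of the 3 dose values against 0, and the slope on dose in mM. Calls needed a Benjamini-Hochberg adjusted p under 0.05 over the 2587 features. The mean test had 2 residual degrees of freedom and a prior of 5.64, the slope test 1 and 16.2, so the spread came mostly from the pooled prior. The control was treated as 1 sample, although the sources used here do not say that it was 1 RNA pool, and the test against 0 leaves out its spread. SDs are over the 3 dose values, and standard errors are limma's moderated ones. Single doses were counted at a log ratio of at least 0.3 with the same sign on both arrays. Agreement between doses was set beside 20 simulations of unchanged samples, which assume 1 control shared by all arrays, with the same spread as each sample.

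Gene lists were fixed by symbol before the data were examined, 32 in all. Of these, 20 had named members and 9 had at least 3 tested. Those 9 were tested with camera (preset correlation 0.01, and an estimated correlation as an alternative) against the 131 named genes, with percentiles from 10000 random lists. The symbol panB in the proteasome list is also that of a pantothenate synthesis gene, and the camera results were computed without it too.

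The rule for named genes was fixed at the same time. It took the 12 largest means each way with a symbol, past the threshold and with the same sign on all 6 arrays, plus the 2 largest each way without a symbol. It also took all members of the metal uptake, metal regulator and metal efflux lists, the 2 to 4 largest members of every other list described, the 5 largest called slopes each way, and the 3 largest values each way at each dose with the same sign on both arrays. Genes outside it were chosen after their values were seen.

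On simulated data with 200 of 2587 features changed, the mean test recovered 97% of 100 features changed by 0.1 and 100% of 100 changed by 0.2, with 13 false among 210 calls. The slope test recovered 91% of 100 at 0.3 per mM and 100% of 100 at 0.6 per mM, with 16 false among 207 calls. The list test on 131 genes called the 1 list that had been shifted by 0.1 and no other. The simulated doses had independent errors, no spread of a shared control, and a dye part equal on both arrays of a dose. False calls from a shared control or from a dye part that does not cancel are therefore not in these counts.

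Alternatives chosen before the data were examined were centring each array on its median, scaling to equal median absolute deviation, medians over spots, all 6 arrays with dose as a random block, with and without a dye term, robust eBayes, a plain one-sample test, stricter thresholds, a filter on dye-swap disagreement over the 90th percentile, other dose scales, other list tests, and each array or dose left out. Alternatives added later kept the exact 0 values, removed a loess trend on the common part (span 0.4) or a position trend (span 0.1), used 1 block of the array, left the swapped arrays unturned, removed the dye part of the other doses when an array was left out, used all features as list background, or left out panB. Figures were drawn with matplotlib 3.10.9.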

Results

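Halobacterium salinarum NRC-1, an archaeon that grows in saturated brine, was taken at mid-log phase (OD600 of 0.5 to 0.6) and exposed for 5 h to manganese sulphate. There were 3 exposed samples, 1 each at 0.8, 1.0 and 1.5 mM. Total RNA of each was compared with a standard control on 2-colour arrays, once with the exposed RNA in Alexa 532 and once with it in Alexa 647, which gave 6 arrays. Each array held 10752 spots for 2688 features at 4 spots per feature, and 2587 features had a value at every dose. The annotation used here named 133 genes, of which 131 were tested. Every other feature is identified by the number of its first spot. The values are the log ratios the authors deposited, with base and centring not given in the sources used here. Array medians ran from 0.0866 to 0.116. A log ratio of 0.1 would be 1.26-fold on a log10 scale and 1.07-fold on a log2 scale. The number of arrays limits the precision. A positive value is likely exposed over control, since the labels word each array as channel 1 against channel 2. They do not state the numerator, and with the opposite one every "higher" below would read "lower". The results below also rest on turning the arrays with manganese RNA in channel 2. With those arrays left unturned, the set of features called would differ. Nothing states that the samples came from separate cultures, so p-values measure the spread between these 3 samples, which may be technical. The samples also differ in dose, so in the test of the mean any response to dose counts as spread. The control was treated as 1 sample, so its own spread is not in any test. Whether it was 1 RNA pool is not given in the sources used here.

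The first comparison asked which genes differed from the standard control across the 3 manganese doses. Transcripts of both named ribosomal proteins fell: rpmC, for large-subunit protein L29, had a mean log ratio of -0.152 ± 0.00672 (SD, n = 3), and rpl12p, for a protein of the ribosomal stalk, one of -0.135 ± 0.0227 (SD, n = 3). The enolase gene eno (-0.133), the Hsp70 chaperone gene dnaK (-0.118), the translocon gene secY (-0.106) and gdhA1, for a glutamate dehydrogenase (-0.140), also fell. So did arcC and arcA of arginine fermentation (-0.117 and -0.0925). The transducer gene htr8 rose to 0.126 ± 0.0156 (SD, n = 3), and hisG, for the first enzyme of histidine synthesis, to 0.0820 ± 0.0183 (SD, n = 3). All of these had the same sign on all 6 arrays, which the rule for naming genes required.

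**Figure D1:**
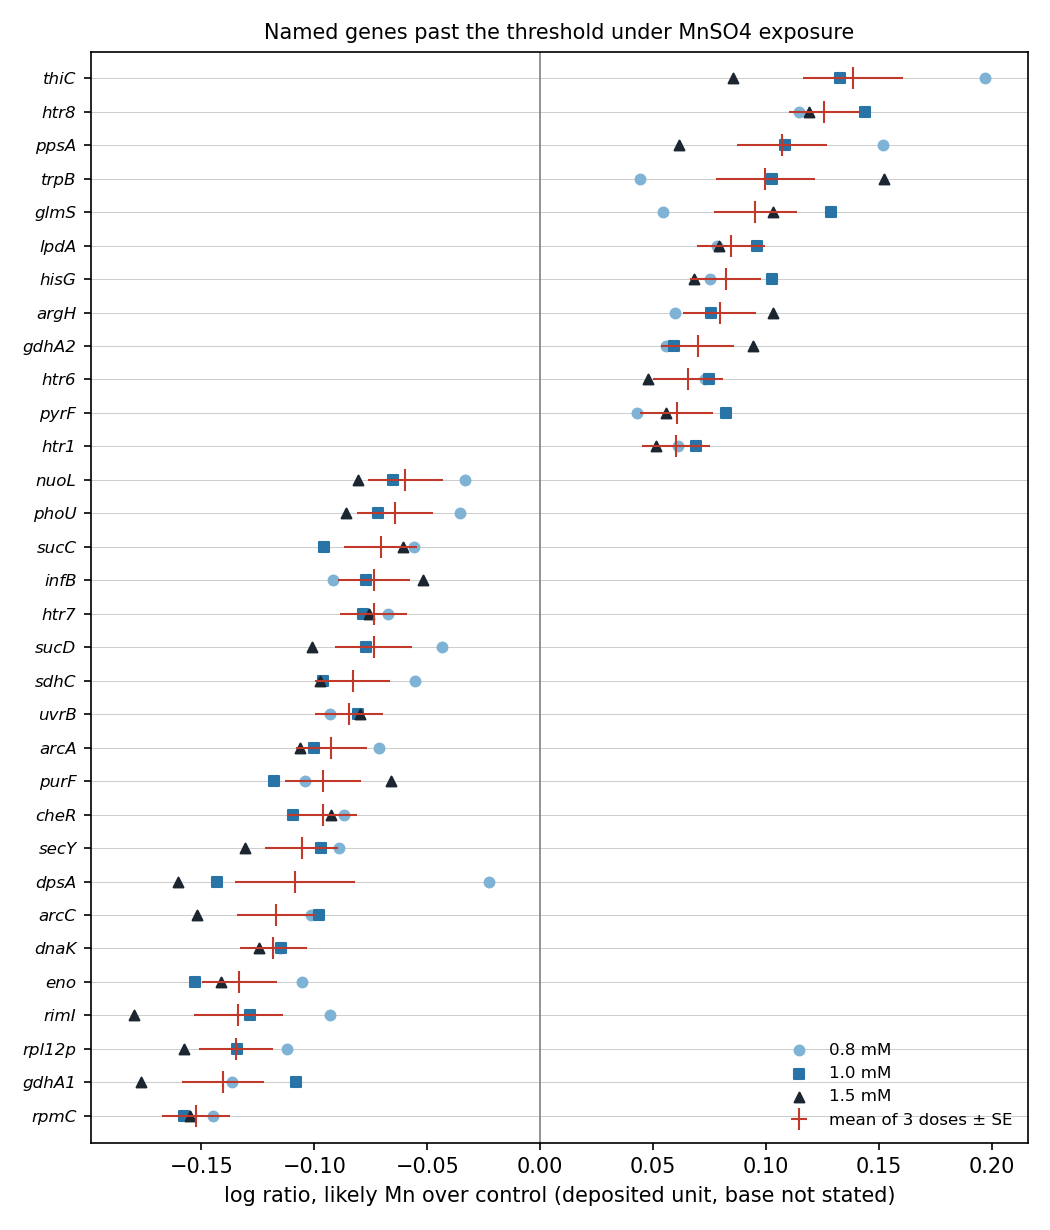
Log ratios (x axis, deposited unit, likely exposed over control) of the 32 named genes past an adjusted p of 0.05, 1 gene per line; symbols are the values at 0.8, 1.0 and 1.5 mM, and red lines the mean of the 3 doses with its moderated standard error. The means run from -0.152 for rpmC to 0.138 for thiC, and every dose of a gene lies on the same side of 0.

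By limma's moderated test of the 3 dose values against 0 with Benjamini-Hochberg adjustment, adjusted p was 0.000515 for rpmC, 0.00141 for rpl12p, 0.00156 for htr8, 0.00159 for eno, 0.00166 for dnaK and 0.00174 for gdhA1. It was 0.00324 for arcC, 0.00390 for secY, 0.00640 for arcA and 0.0107 for hisG. The rule for naming genes also took rimI, for an acetyltransferase (-0.134, adjusted p = 0.00323), the chemotaxis methyltransferase gene cheR (-0.0963, adjusted p = 0.00453), the excision repair gene uvrB (-0.0845, adjusted p = 0.00749) and dpsA, for a ferritin-like iron-binding protein. dpsA was at -0.0229, -0.143 and -0.160 from the lowest to the highest dose, with a mean of -0.109 ± 0.0748 (SD, n = 3) and an adjusted p of 0.0282. Only 2 named genes passed upward with the same sign on all 6 arrays, against 16 downward, so the rule filled 12 places for genes that fell and 2 for genes that rose.

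Larger differences lay among features without a gene name here. The features at spots 1007 and 1485 rose to 0.387 ± 0.0244 and 0.293 ± 0.0237 (SD, n = 3), and those at spots 1605 and 1849 fell to -0.390 ± 0.0697 and -0.369 ± 0.0684 (SD, n = 3). The value at spot 1605, the farthest from 0 of all features tested, would be a 2.46-fold difference on a log10 scale and a 1.31-fold one on a log2 scale.

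Of the 2587 features, 497 passed (19.2%), 292 higher and 205 lower, and 982 had an unadjusted p under 0.05. Among the 131 named genes, 12 were higher and 20 lower, or 15 and 22 when adjusted over the named genes alone. With arrays scaled to equal spread the calls were 303 higher and 327 lower, so the share of higher calls was 48.1% there against 58.8% as deposited. All 32 named calls were kept after centring each array on its median, and 31 after scaling, where pyrF was lost. Without the 1.0 mM sample, 64 features were higher and 70 lower, and 8 of the 32 named calls were kept, those of htr8, rpmC, gdhA1, rpl12p, rimI, eno, dnaK and arcC. Leaving out any 1 of the 6 arrays left 0 calls with limma, with 200 to 539 features at an unadjusted p under 0.05, because the dye part of that dose then no longer cancelled. A plain one-sample test per gene also made 0 calls, with 613 at an unadjusted p under 0.05.

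Of the 32 named calls, 18 had the same sign on all 6 arrays, and 14 did not, 10 of them higher and 4 lower. With manganese RNA in Alexa 532 and in Alexa 647, the means were -0.00164 and -0.190 for purF, 0.0183 and -0.166 for infB, -0.149 and 0.0301 for nuoL, 0.348 and -0.228 for pyrF, 0.393 and -0.194 for trpB, and 0.237 and -0.0972 for gdhA2. They were -0.0226 and 0.181 for argH, -0.0113 and 0.180 for lpdA, -0.0110 and 0.142 for htr6, 0.00199 and 0.118 for htr1, and 0.0194 and 0.195 for ppsA. These 11 means moved by over 1.5 times when 1 array was left out with the dye part left in. They were -0.0525 for purF and -0.0385 for infB without replicate 2 at 1.0 mM, -0.0233 for nuoL without replicate 1 at 0.8 mM, and 0.0108 for gdhA2 without replicate 1 at 1.0 mM. Without replicate 2 at 1.5 mM they were 0.0405 for argH, 0.0479 for lpdA, 0.0368 for htr6, 0.0376 for htr1 and 0.0675 for ppsA. pyrF and trpB turned to -0.0428 and -0.0105 without replicate 1 at 1.5 mM. The arrays that moved a mean by that much numbered 6 for pyrF, trpB and gdhA2, 4 for nuoL, 3 for infB, 2 for purF, argH, lpdA and htr6, and 1 for htr1 and ppsA. The other 3 of the 14 were sucD, glmS and thiC.

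**Figure D2:**
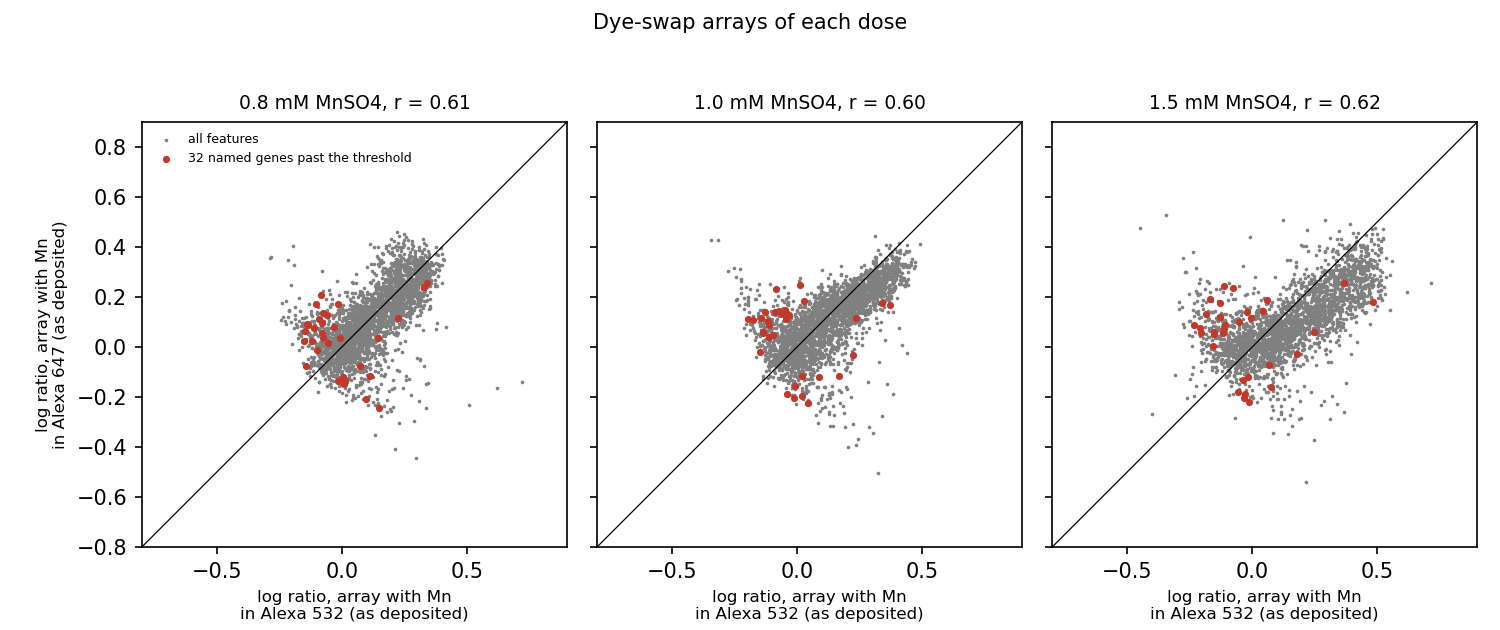
Deposited log ratios of the 2 arrays of each dose, the array with manganese RNA in Alexa 532 on the x axis and that with it in Alexa 647 on the y axis; grey points are all features and red points the 32 named genes past the threshold. The arrays correlate at 0.61, 0.60 and 0.62 along the diagonal, which is the part common to both dye orientations, and the named genes that fell lie above the diagonal and those that rose below it.

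The second comparison asked whether functional groups moved together. The tricarboxylic acid cycle list had 6 measured members, of which 0 rose, 3 fell and 3 did not pass. The members that fell were sdhC, for a succinate dehydrogenase subunit (-0.0831, adjusted p = 0.0121), and sucD and sucC, for the subunits of succinyl-CoA synthetase (-0.0738 and -0.0707, adjusted p = 0.0235 and 0.0223). The citrate synthase gene citZ was at -0.0381 and did not pass. The median of the list lay at percentile 5.58, 1.07 and 3.63 of random lists of named genes at 0.8, 1.0 and 1.5 mM. The camera test of the list gave an adjusted p of 0.0848, and 0.868 with an estimated correlation. Against all features as background, a setting added after the data were seen, the adjusted p was 0.00414.

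Of 14 amino acid synthesis genes, 3 rose, 0 fell and 11 did not pass. These were trpB of tryptophan synthase (0.0996, adjusted p = 0.0185), hisG, and argH, for argininosuccinate lyase (0.0794, adjusted p = 0.0136). The list median lay at percentile 98.6, 92.4 and 98.8 at 0.8, 1.0 and 1.5 mM. The camera adjusted p was 0.0954, and 0.868 with an estimated correlation. The same counts held when adjusted over the list alone, for this list and for the tricarboxylic acid cycle. trpB averaged -0.0105 without replicate 1 at 1.5 mM.

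Of 11 chemotaxis and transducer genes, 3 rose, 2 fell and 6 did not pass, or 3 and 3 when adjusted over the list alone. The transducer genes htr8, htr6 (0.0653, adjusted p = 0.0251) and htr1, for the transducer of sensory rhodopsin I (0.0602, adjusted p = 0.0303), were higher, while htr7 (-0.0738, adjusted p = 0.0133) and cheR were lower. Without the 0.8 mM sample the adjusted p was 0.0665 for htr6 and 0.0750 for htr1. The transducer gene htr18 was at -0.0595 (adjusted p = 0.0812, or 0.0188 after centring). Among 12 purine and pyrimidine synthesis genes, pyrF rose (0.0603, adjusted p = 0.0365), purF, for the first committed enzyme of purine synthesis, fell (-0.0960, adjusted p = 0.00699), and 10 did not pass; the counts adjusted over the list alone were the same. pyrF had an adjusted p of 0.241 after scaling, and its mean was negative without replicate 1 of any dose. The camera adjusted p was 0.858 for both lists.

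None of the 12 aminoacyl-tRNA synthetase genes passed, although cysS was at 0.0601 (adjusted p = 0.0867) and aspS at -0.0436 (adjusted p = 0.0896, or 0.0438 after centring). Of 5 DNA repair genes 1 fell, uvrB, while uvrA was at 0.0415 (adjusted p = 0.134), and 4 did not pass. None of 4 proteasome genes, 4 genes of the cobalamin synthesis and cobalt list and 4 of the bacteriorhodopsin and retinal group passed. psmA was at -0.0101 and cbiQ, of the cobalamin and cobalt list, at -0.0525 (adjusted p = 0.0603, or 0.0266 after centring). The halorhodopsin gene hop was at 0.0414 (adjusted p = 0.0982, or 0.0297 after scaling). The camera adjusted p was 0.858 for each of these 5 lists. Counts adjusted over each list alone were the same. Of the 9 lists with at least 3 measured members, 0 passed with camera, and 2 had an unadjusted p under 0.05, the tricarboxylic acid cycle and amino acid synthesis. With an estimated correlation the smallest adjusted p was 0.868.

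The other 11 lists had 1 or 2 measured members and are given as values. Both ribosomal proteins and both arginine fermentation genes fell, as described. dnaK fell and its partner dnaJ was at -0.0176 (adjusted p = 0.501). The translation initiation factor gene infB fell to -0.0736 (adjusted p = 0.0181), and nuoL of the respiratory complex I-like enzyme to -0.0597 (adjusted p = 0.0414). Without the 1.5 mM sample nuoL had an adjusted p of 0.0729, and with manganese RNA in Alexa 647 it was at 0.0757 and 0.0187 at 0.8 and 1.0 mM. infB had an adjusted p of 0.0522 without the 0.8 mM sample. dpsA was the only measured member of the iron list. phoU, a regulator gene listed with metal-dependent regulators and with phosphate uptake, fell to -0.0643 (adjusted p = 0.0337), and its adjusted p was 0.0562 without the 1.5 mM sample. phnE of phosphonate uptake was at 0.0110 (adjusted p = 0.632). The methionine sulfoxide reductase gene msrA, the only member for oxidative stress defence, was at -0.0137 (adjusted p = 0.530). The molybdopterin genes moaA and moaC were at -0.00974 and -0.000465, and the replication initiator genes orc7 and orc8 at 0.0332 and 0.0198; none of these 4 passed. Manganese and zinc uptake and metal efflux, the groups closest to the treatment, had no member under a gene name and were not analysed here. The same holds for general transcription factors, RNA polymerase, ATP synthase, terminal oxidases, gas vesicles, the archaellum, potassium and sodium transport, transposases and the replicons pNRC100 and pNRC200.

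The third comparison took each dose alone, with 1 sample, 2 technical arrays and no test. Features at least 0.3 from 0 with the same sign on both arrays numbered 5 higher and 3 lower at 0.8 mM, 7 and 2 at 1.0 mM, and 3 and 4 at 1.5 mM. csg, the gene of the surface-layer glycoprotein that forms the cell envelope, was the only named gene among the 3 farthest from 0 in either direction at any dose. It stood at 0.391 at 0.8 mM, where its arrays gave 0.620 and 0.163. The features at spots 1605 and 1849 were among the 3 lowest at every dose, at -0.323 and -0.300, then -0.387 and -0.371, then -0.462 and -0.437 with rising dose. They were joined by spot 189 at 0.8 mM (-0.320) and 1.5 mM (-0.317), and by spot 4007 at 1.0 mM (-0.291). Spot 1007 was among the 3 highest at every dose (0.370, 0.415 and 0.377). It was joined by spot 1555 at 0.8 mM (0.430), spots 1407 and 3133 at 1.0 mM (0.324 and 0.313), and spots 171 and 1485 at 1.5 mM (0.313 and 0.308). With single arrays in place of pairs, 154 to 617 features reached 0.3, since the dye part then stayed in the value.

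The fourth comparison asked how alike the doses were. Across the 2587 features, which are not independent replicates, the profiles correlated at 0.771 between 0.8 and 1.0 mM, 0.740 between 1.0 and 1.5 mM and 0.592 between 0.8 and 1.5 mM (Spearman 0.654, 0.602 and 0.478). Unchanged samples simulated against 1 shared control gave 0.501. The covariance was 0.00274, 0.00333 and 0.00251 in the same order, against 0.00103 simulated. The same sign was seen for 74.4%, 73.1% and 67.8% of features, against 66.6% simulated. These simulated values assume that all arrays shared 1 control with the same spread as each sample. That assumption, and not the data, sets the simulated correlation and share of 1 sign. The control's own spread was not measured. The control was not split, so part or all of the excess may come from it. A remnant of the part common to both dye orientations may add to it too. That part correlated at 0.942 to 0.963 between doses, and with the dose values at 0.00206, 0.197 and 0.382 at 0.8, 1.0 and 1.5 mM. How much it adds was not tested.

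The fifth comparison asked which genes followed the dose. The named gene with the steepest slope was csg, which went from 0.391 at 0.8 mM to 0.135 at 1.0 mM and -0.0980 at 1.5 mM, a slope of -0.654 ± 0.0625 per mM (SE, 3 samples). gdhB, for a glutamate dehydrogenase (-0.304 ± 0.0717), and the ferredoxin gene fer2 (-0.171 ± 0.0456) also fell with dose. The histidine degradation genes hutU and hutI (0.196 and 0.165), the NAD synthesis genes nadC and nadA (0.183 and 0.156) and deoC, for deoxyribose-phosphate aldolase (0.205), rose. All 8 slopes are per mM, and gdhB, fer2, hutU, hutI, nadC, nadA and deoC were chosen after their values were seen. Adjusted p was 9.06e-06 for csg with limma and between 0.0169 and 0.0445 for the other 7. With all 6 arrays in 1 fit and dose as a random block, no slope passed, that of csg included. After each array was centred on its median, hutU had a slope of 0.169, nadC of 0.156, gdhB of -0.331 and fer2 of -0.198 per mM, and none of the 7 was past the threshold. Removal of a trend on the part common to both dye orientations, a setting added after the data were seen, took hutU from 0.196 to 0.111, hutI from 0.165 to 0.0881, nadC from 0.183 to 0.101, nadA from 0.156 to 0.0795 and deoC from 0.205 to 0.119. It took gdhB to -0.228 and fer2 to -0.143, and again none of the 7 passed (adjusted p of 0.216 to 0.432). The part common to both dye orientations was 0.235 to 0.321 for the 5 genes that rose. Across all features the dose values correlated with that part at 0.00206, 0.197 and 0.382 at 0.8, 1.0 and 1.5 mM (Spearman 0.0147, 0.265 and 0.447). Turning and averaging therefore left an association with it at the higher doses. A remnant of the dye part that grows with dose was not told apart from a rise with dose in such genes.

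The falls of csg and gdhB lay mostly in 1 dye orientation. On the arrays with manganese RNA in Alexa 532 csg was at 0.620, 0.108 and -0.309 with rising dose, a slope of -1.23 per mM. On those with it in Alexa 647 it was at 0.163, 0.161 and 0.113, a slope of -0.0764 per mM. gdhB was at 0.278, -0.122 and -0.191 on the first set, a slope of -0.567 per mM, and at 0.191, 0.146 and 0.153 on the second, a slope of -0.0413 per mM. Among unnamed features the steepest falls were at spots 1555 (-0.700), 2811 (-0.512), 1995 (-0.380) and 383 (-0.348), and the steepest rises at spots 3405 (0.341), 213 (0.270), 2511 (0.267), 3615 (0.266) and 61 (0.253). With manganese RNA in Alexa 532 and in Alexa 647, the slopes were -1.53 and 0.129 at spot 1555, -0.982 and -0.0411 at spot 2811, -0.752 and -0.00744 at spot 1995, and 0.733 and -0.0510 at spot 3405. The slopes were -0.575 and -0.121 at spot 383, 0.426 and 0.106 at spot 3615, 0.418 and 0.0876 at spot 61, 0.398 and 0.142 at spot 213, and 0.378 and 0.157 at spot 2511. Among the named genes that rose, hutI had 0.249 and 0.0813, while nadA had 0.153 and 0.158.

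**Figure D3:**
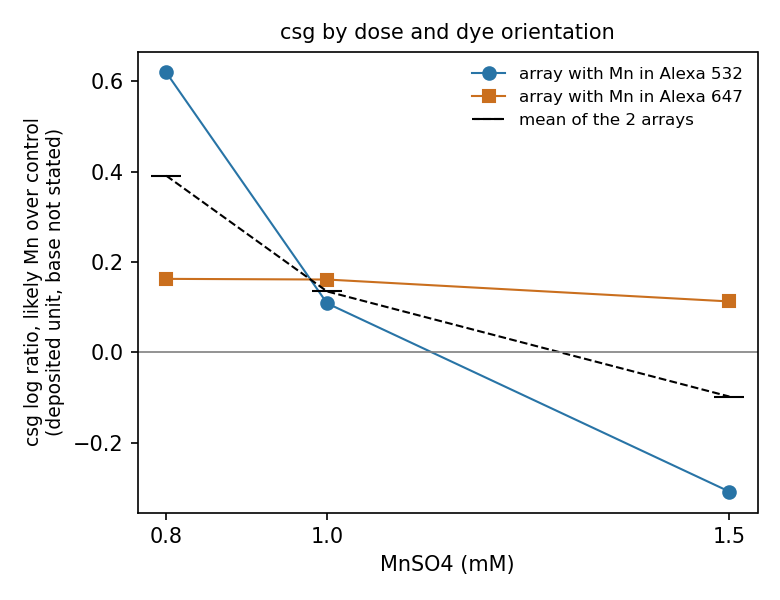
Log ratio of csg (y axis, deposited unit, likely exposed over control) against manganese sulphate dose (x axis, mM), for arrays with manganese RNA in Alexa 532 (circles), in Alexa 647 (squares) and their mean (dashed line); each point is the mean of 4 spots on 1 array. The values fall from 0.620 to -0.309 in the first orientation and from 0.163 to 0.113 in the second.

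With limma, 156 features rose with dose and 35 fell, and 601 had an unadjusted p under 0.05. The number of calls changed with the level of whole arrays. The median of all features was 0.00582 at 0.8 mM, 0.0111 at 1.0 mM and 0.0292 at 1.5 mM. After centring, 1 feature rose and 6 fell, all 7 of them among the 191, and csg was the only named gene kept (adjusted p = 0.000889). The slopes themselves moved little, from a median of 0.181 to 0.154 per mM for the 156 that rose and from -0.237 to -0.264 for the 35 that fell, and all 191 had an unadjusted p under 0.05. At that unadjusted level 470 features rose and 131 fell as deposited, against 282 and 269 after centring, which sets the median slope near 0, and 80 and 203 after scaling. Leaving out 1 array gave 0 calls for 5 of the 6 arrays, with 2 to 845 features at an unadjusted p under 0.05, and 1159 rising and 66 falling features without replicate 2 at 1.5 mM.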

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

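The tests on centring, on a trend on the common part, on a position trend and on the slope of csg per dye orientation, and the shuffles, were chosen after the results were seen. Each item here has a slope on dose that limma called, a difference between doses of the same contrast. The named ones are csg (-0.654 per mM), gdhB (-0.304), fer2 (-0.171), deoC (0.205), hutU (0.196), nadC (0.183), hutI (0.165) and nadA (0.156). Those without a name are spots 1555 (-0.700), 2811 (-0.512), 1995 (-0.380), 383 (-0.348), 1605 (-0.190), 1849 (-0.183), 3405 (0.341), 213 (0.270), 2511 (0.267), 3615 (0.266) and 61 (0.253).

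The fall of csg was present on all 4 of its spots, the slope nearest 0 being -0.641 per mM, which argues against a few aberrant spots. The slope kept an adjusted p of at most 0.0108 after centring and after removal of a position trend, which argues against those as the whole cause. After a trend on the common part was removed the slope was -0.576 ± 0.0798 per mM (SE) against -0.654 ± 0.0625 before, and the adjusted p rose to 0.143. The slope was smaller, its SE larger and the prior degrees of freedom 6.30 against 16.2. The largest p that passed the adjustment also fell, from 0.00368 to 1.79e-06. In the fit of all 6 arrays with dose as a random block no slope passed. The slope on the arrays with manganese RNA in Alexa 647 was 6.20% of that on the arrays with it in Alexa 532. A candidate explanation is therefore an effect of 1 dye orientation, such as a saturated channel, and a response of the surface-layer gene to dose stays open, as the fall in the other orientation was small (-0.0764 per mM).

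The calls on dose leaned to rising features, 156 against 35, and a shift of whole arrays stays open for that lean, since centring sets the median slope near 0 and so cannot test it. Such a shift is too small for the slopes of the calls: centring took the median slope of the rising calls from 0.181 to 0.154 per mM (median SE 0.0456 and 0.0443). Centring lowers every slope by the same amount, so that all 35 falling ones steepened follows from arithmetic. After centring 7 calls were left. The prior degrees of freedom fell from 16.2 to 10.1, and the largest p that passed was 0.000115. Of the 156 rising and 35 falling calls, 54 and 34 had a p within the largest that passed before (0.00368). Which of these changes lost the calls was not tested. Removing a trend on the common part left the falling calls at a median slope of -0.237 per mM (median SE 0.0571, -0.237 and 0.0523 before). This argues against a bias that follows the common part as the source of their slopes. Such a bias stays open for the rising calls, left at 0.107 per mM (median SE 0.0397) there and at 0.101 (median SE 0.0440) with arrays scaled to equal spread. In either setting 1 call passed. A bias tied to brightness itself stays open for both, since no intensities were used. An effect of 1 dye orientation stays open too. The median slope of all features was 0.0362 per mM with manganese RNA in Alexa 532 and 0.00374 with it in Alexa 647. For the rising calls these medians were 0.295 and 0.0832 per mM, and for the falling calls -0.436 and -0.0988. The 87.4% of calls with 1 sign in both orientations decide little. In 20 shuffles of one orientation against the other that share was 77.0% to 84.3%, which showed the 80% set beforehand to be too low a bar. Spots listed at exactly 0 stay open: 3.64% of features without such a spot were called rising, against 6.03% of all. The 2251 features without such a spot are most of all those tested, so the share among the rest was well above 6.03%. Array batch, which cannot be separated from dose, and a true dose response stay open too.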

How the results depend on the processing

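Settings not named in the methods as chosen beforehand were added after the data were seen, and the cause of a change was not tested unless given here. Counts of features higher and lower than the control (292 and 205) stayed within 1.5 times of these under medians over spots, robust eBayes, both fits of 6 arrays, the dye-swap filter, exact 0 values kept and the position trend removed. They were 104 and 119 at an adjusted p under 0.01, and 18 and 13 at an adjusted p under 0.05 with a mean of at least 0.2 in size. A plain one-sample test, which has no pooled spread, gave 0 and 0. Both fits of 6 arrays enter each technical array as its own value and add no samples. How far the block for dose took up the spread between samples was not tested. The counts and the named calls kept in those fits are therefore no separate support. The lower count was 327 after scaling and 334 after the trend on the common part was removed, and the higher count was 112 with the second block of the array alone. Unturned arrays, the reading under the rule written beforehand, gave 1753 and 346. Those values hold the part common to both orientations, taken here as a dye part, and the genes called under that reading are not described. Leaving out arrays or doses gave 0 to 575 higher and 0 to 244 lower.

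Counts of features rising and falling with dose (156 and 35) were 29 and 12 on log2 dose and 0 and 4 on ranked dose. They were 1 and 6 after centring, and 0 and 1 after scaling or without the trend on the common part. With 6 arrays in 1 fit they were 0 and 0 (692 at an unadjusted p under 0.05), as with exact 0 values kept (347). They were 35 and 8 without the position trend, and 57 and 26 or 33 and 13 from the first or second block of the array. Robust eBayes gave 142 and 20. Leaving out arrays gave 0 to 1159 rising and 0 to 76 falling.

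Features past the size rule (8, 9 and 7 at 0.8, 1.0 and 1.5 mM) numbered 30, 36 and 43 at a size of 0.2 and 0, 0 and 0 at 0.5. Single arrays gave 230 to 262, 154 to 435 and 283 to 617. Correlations between doses of 0.771, 0.592 and 0.740 became 0.654, 0.478 and 0.602 by Spearman and, over features with a mean above the median in size, 0.848, 0.708 and 0.842. Of the lists, 0 passed in every setting except all features as background, where 1 passed, the tricarboxylic acid cycle.

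Of the 32 named calls, 32 were kept with a dye term and after the position trend was removed, 30 with dose as a block, 27 with exact 0 values kept (dpsA, phoU, nuoL, trpB and pyrF were lost), 28 and 19 with the first and second block of the array, and 29, 8 and 30 without the 0.8, 1.0 and 1.5 mM sample. With an array left out and the dye part of the other doses removed, 10 to 32 were kept and 0 changed sign. With the dye part left in, pyrF turned to -0.0389, -0.0254 and -0.0428 without replicate 1 at 0.8, 1.0 and 1.5 mM, and trpB to -0.0105 without replicate 1 at 1.5 mM; without replicate 2 at 1.5 mM they were highest, at 0.163 and 0.210. What signal over background limits is unknown, since no intensities were used.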

Other observations

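The test of pairs far apart on the array was chosen after the result was seen. Several named genes outside the lists or outside the naming rule also passed, and all were chosen after their values were seen. Of the 3 named glutamate dehydrogenase genes, 2 passed, in opposite directions: gdhA1 was at -0.140 ± 0.0346 and gdhA2 at 0.0697 ± 0.0213 (SD, n = 3), with limma adjusted p of 0.00174 and 0.0234. The third, gdhB, did not pass (0.0758, adjusted p = 0.239) and was at 0.234, 0.0122 and -0.0191 from the lowest to the highest dose. In central carbon metabolism, ppsA, for phosphoenolpyruvate synthase, rose to 0.107 ± 0.0453 (SD, n = 3; adjusted p = 0.00941), while eno, of the adjacent glycolytic step, fell. The thiamine synthesis gene thiC had the highest mean of the 32 named genes past the threshold at 0.138 ± 0.0559 (SD, n = 3; adjusted p = 0.00473), with 0.197, 0.133 and 0.0855 from the lowest to the highest dose. glmS, for an amidotransferase that makes glucosamine phosphate (0.0953, adjusted p = 0.0112), and lpdA, for dihydrolipoamide dehydrogenase (0.0844, adjusted p = 0.00783), also rose. None of gdhA2, ppsA, thiC, glmS and lpdA had the same sign on all 6 arrays, and none stayed past the threshold without the 1.0 mM sample.

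Named genes that are neighbours in the genome had similar values. In the gene order of strain 91-R6, 27 pairs of named genes were adjacent or had 1 gene between them. Their mean log ratios differed by 0.0348 on average, against 0.0643 for shuffled genes (one-sided permutation test with 100000 shuffles, p = 0.00044). Pairs such as sucC and sucD (-0.0707 and -0.0738), arcA and arcC (-0.0925 and -0.117), nadC and nadA (0.0447 and 0.0478) and hutI and hutU (0.0387 and 0.0379) lay close together. The pairs that differed most were lpdA and leuS (by 0.126), dnaK and dnaJ (0.101), lpdA and pheA (0.0945), hisB and fer2 (0.0927) and hisA and fer2 (0.0803). The hypothesis that neighbouring genes change together, as transcription from shared promoters would give, was stated before this test was run. Many pairs were also printed near each other, with a median of 16 features between them on the array. Removing a position trend left the difference at 0.0342 (permutation p = 0.00039), but the 7 pairs over 300 features apart gave a difference of 0.0370 with a permutation p of 0.0726. Their difference was close to that of all 27 pairs, but 7 pairs are too few to decide. Whether printing near each other accounts for part of the similarity stays open.

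Of the 4 sign assignments of the 3 doses, counting mirror images once, 1 gave as many calls, the real one with 497, and the highest of the others gave 0. With 4 assignments no share under 0.05 is possible. All 497 calls had 1 sign at the 3 doses, and unchanged samples simulated against a shared control already correlated at 0.501, so the real assignment is favoured with or without an effect of manganese.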
